A study of Homo sapiens with 2 samples.

How the data were processed

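RNA sequencing of the A549 line was analysed in 2 libraries, 1 from cells carrying the empty vector and 1 from cells overexpressing PKP2 with an SFB tag. Both cultures were at passage 5, per the labels. RNA was extracted with Trizol, and the libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. Each library has its own file with a value per gene, listed by Entrez ID, and no column of another sample was used.

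The values deposited by the authors are estimated counts per gene, called counts in the file headers. Their differing totals show that they were not set to a common depth. The totals say nothing on length, and the values were taken as unscaled counts from the headers and the values themselves. Of the 16399 genes listed, 2403 in the vector library and 2491 in the PKP2 library had a fractional value, as a counter that divides reads between similar genes or transcripts gives. HISAT2 2.0.4, Bowtie2 and RSEM 1.2.12 and the genome build GRCh38.p12 are named per the submitters' processing notes. Which aligner fed the counting, the annotation release, the filters, the strand setting and the read layout are not given in the sources used here. Genes that share reads with a paralog, a pseudogene or an overlapping or antisense gene are therefore uncertain, and genes with a fractional count are marked as such below. No listed gene was at 0 in both libraries.

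From the estimated counts, CPM, the count per 1000000 counts of the library total, was computed. The totals were 16996976 for vector and 16808842 for PKP2. A gene was called expressed at 1 CPM or more in at least 1 library. The difference was log2(CPM + 1) in the PKP2 library minus that in the vector library, and it understates the difference of genes near 1 CPM. A gene counted as at least 2-fold higher or lower where this difference was 1 or more in size, and the smaller steps counted at 1.5-fold were set on the same scale. The fold printed for a gene is the plain ratio of CPM, so a gene of low level may have a ratio over 2 and not be counted. Its interval is an exact 95% Clopper-Pearson interval from counts rounded to whole numbers. For a gene at 0 the fold was bounded with a floor of 3 counts, 0.177 CPM in the vector library and 0.179 CPM in the PKP2 library. Intervals and floors cover counting error only. With 1 library per group there is no replicate check of any difference, no p-value was computed, and every comparison is between these libraries and not between the conditions.

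Before the data were examined, 30 gene lists were fixed from general knowledge. They covered desmosomes, adherens and tight junctions, mesenchymal genes, Wnt targets, DNA repair, EGFR and ERK signalling, immediate early genes, YAP targets, integrins, p53 and NRF2 targets, cell cycle, stress, interferon and NF-kappaB responses, hypoxia, cholesterol synthesis, markers of other cell types, RNA quality and housekeeping. For each list the median difference of its expressed members was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these libraries and is not a p-value. Lists with under 3 expressed members received none. The 95% counting interval of a list median came from 500 redrawn count sets. A list was described as standing apart below percentile 2.5 or above percentile 97.5.

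The genes named in the text were chosen by a rule set in advance. It takes PKP2, then the 12 genes with the largest positive and the 12 with the largest negative difference among those with a mean of 5 CPM or more and a symbol. From each list it takes up to 4 members with the largest difference in size at a mean of 5 CPM or more, or at 1 CPM or more where a list has fewer such members. LIG4, CTNNB1, AXIN2, MYC, CCND1 and EGFR were included whatever their values. Some genes that the rule takes are not reported here. Any other gene is said to have been picked after its value was seen.

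Symbols were matched by Entrez ID to a RefSeq gene table of assembly GRCh38.p14, used for names only, and 16183 of 16399 IDs matched. The 216 IDs without a symbol held 0.0708% of the vector counts and 0.0657% of the PKP2 counts. Coordinates on GRCh38, the length of the longest transcript and its GC content came from GENCODE release 29. Length and GC were found for 98.8% of the expressed genes.

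The difference between the libraries followed transcript length and GC content. After this was seen, an additive lowess trend on length and GC with a span of 0.3 was estimated and removed as an added alternative, random lists were also matched on length, and genes with fractional counts were left out. The alternatives set in advance were pseudocounts of 0.1 and 5, no filter, a mean of 5 CPM or more, thresholds of 1.5-fold and 4-fold, and scaling that set the median or the trimmed mean (30% trimmed on the ratio and 5% on the level) of the log ratios to 0.

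The calculation was tested on simulated counts for the 16399 genes of the PKP2 and vector comparison, drawn with counting error only and 200 genes altered at each size. It called 0% of the genes altered 1.5-fold, 94.5% of those altered 2.5-fold and 100% of those altered 4-fold as at least 2-fold different, with 0 unaltered genes called. Between 95.2% and 95.7% of the counting intervals held the simulated ratio. The altered genes and the intervals checked were limited to genes with a mean of 5 CPM or more, and all simulated counts were whole. The shares called and held therefore do not cover genes of lower level or fractional counts. Counting error alone was also simulated 100 times for unaltered genes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Mitochondrially encoded mRNAs were not analysed here.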

Results

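Gene expression was measured by RNA sequencing in A549, an established human lung adenocarcinoma line, to look for genes downstream of plakophilin 2 (PKP2). PKP2 is an armadillo-repeat protein of the desmosomal plaque. The vector group and the PKP2 group held 1 library each, so no difference has a replicate check. The estimated counts summed to 16996976 in the vector library and 16808842 in the PKP2 library. In all 15792 and 15816 genes were above 0, respectively, and 12820 genes were expressed at 1 CPM or more in at least 1 library. The 10 most abundant genes held 7.24% of the vector counts and 7.61% of the PKP2 counts.

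PKP2 itself (Entrez ID 5318, chromosome 12, 32790745 to 32896840, minus strand, GRCh38) was 9.82-fold higher in the PKP2 library, at 268 CPM (4505 counts) against 27.3 CPM (464 counts). The 95% counting interval of this ratio was 8.92 to 10.8. The vector library thus held endogenous PKP2 transcripts, and in the PKP2 library gene-level counts do not separate tagged from endogenous transcripts. The other desmosome components did not share this difference. Of the 8 expressed ones, the desmosomal cadherin DSG2 (fractional count) was 1.16-fold lower (1.10 to 1.22), the desmosomal plaque protein DSP 1.12-fold lower (1.05 to 1.19) and PKP4 1.09-fold lower (1.01 to 1.17). DSC3 (fractional count) was 1.17-fold lower with an interval of 0.887 to 1.55, which includes 1. JUP, the plakoglobin of the same plaque, had a ratio of 1.07 (1.02 to 1.11) and PKP3 of 1.09 (0.990 to 1.19), both picked after their values were seen. The median difference of the list was -0.12, at percentile 7.75 of the random lists, and -0.01 with the length and GC trend described below removed. Without that trend the differences were -0.08 for DSG2, -0.02 for DSC3, 0.00 for DSP and -0.03 for PKP4, against -0.21, -0.20, -0.16 and -0.12 with it. JUP lay at 0.02 instead of 0.09 and PKP3 at 0.00 instead of 0.12.

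Apart from PKP2, few genes were far apart between the libraries. By the 2-fold rule 11 genes were higher and 13 were lower in the PKP2 library, where counting error alone gave at most 1 in each direction over 100 simulations. Of these 24 genes, 17 had a fractional count, a share of 70.8% against 18.6% of all expressed genes, and 13 had a mean under 5 CPM. The 7 with whole counts were PKP2, CFB and BARX1 on the higher side and MUC5AC, CEACAM6, LAMA4 and the gene with Entrez ID 643314 on the lower side. BARX1, LAMA4 and Entrez ID 643314 fall outside the naming rule and were picked after their values were seen. With the length and GC trend removed, PKP2, CFB, MUC5AC and CEACAM6 were still past the rule, BARX1 at 0.87 and LAMA4 at -0.91 were not, and Entrez ID 643314 had no value. Of the 11 and 13 genes, 3 and 4 had no length and GC record and could not enter the trend removal. Of the other 8 and 9, 5 and 8 were still past the rule with the length and GC trend removed, and 2 and 3 further genes passed it, 7 higher and 11 lower in all. At 1.5-fold, 94 genes were higher and 101 lower, against means of 13.4 and 14.3 from counting error alone. Across expressed genes, which are not replicates, the Pearson correlation of log2(CPM + 1) was 0.994. The SD of the difference was 0.31 at 1 to 5 CPM and 0.19 at 100 CPM or more, where counting error alone gives 0.23 and 0.037.

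**Figure D1:**
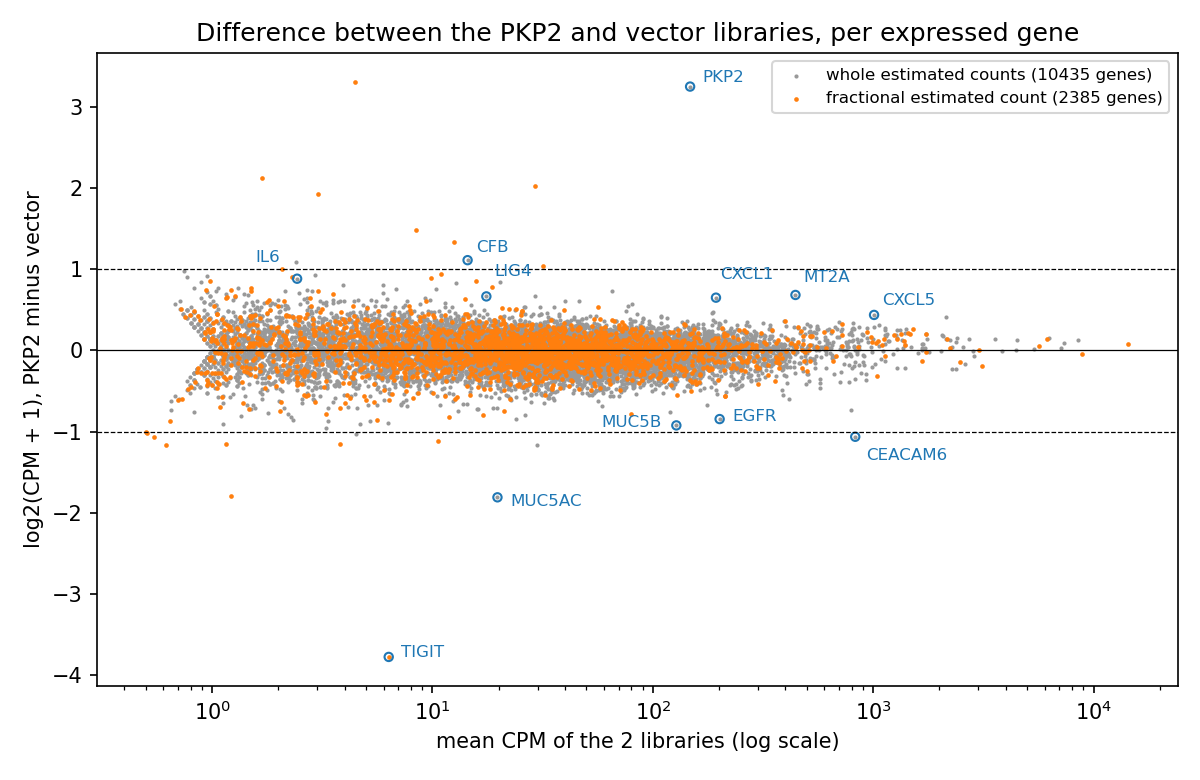
Each point is an expressed gene, with its mean CPM over the 2 libraries on a log axis and the difference in log2(CPM + 1), PKP2 minus vector, on the other axis. Grey points have whole and orange points fractional estimated counts, dashed lines mark the 2-fold rule, and PKP2 lies at 3.25 while most of the 12820 genes lie near 0.

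After PKP2, CFB was the gene with whole counts that was highest in the PKP2 library among those with a mean of 5 CPM or more. CFB, which encodes complement factor B (chromosome 6, 31945650 to 31952084), was 2.29-fold higher (1.89 to 2.80), at 20.1 against 8.77 CPM. IL11, a cytokine of the IL-6 family, was 1.93-fold higher (1.44 to 2.63), and RND1, a small GTPase, was 1.87-fold higher (1.53 to 2.29). COXFA4L3 was 1.85-fold higher (1.58 to 2.17). HLA-B, a class I antigen-presenting molecule with a fractional and therefore uncertain count, was 1.88-fold higher (1.57 to 2.26). The remaining genes of the leading 12 all had fractional counts and are uncertain. They were LOC102723728 at 4.36-fold, LOC102723360 at 2.76-fold, EIF3CL at 2.10-fold, RGPD6 at 2.06-fold, BIVM-ERCC5 at 1.99-fold and LYPD1 at 1.78-fold.

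The 12 genes with the largest negative differences included a pair of secreted mucins, CEACAM6 and EGFR. MUC5AC (chromosome 11, 1157953 to 1201138), a gel-forming airway mucin, was 3.81-fold lower in the PKP2 library (3.15 to 4.62), at 8.21 against 31.2 CPM. MUC5B, its neighbour on chromosome 11 and the other main airway mucin, was 1.91-fold lower (1.79 to 2.03), at 88.1 against 167.7 CPM. CEACAM6, a GPI-anchored adhesion protein and the most abundant gene of this set, was 2.09-fold lower (2.04 to 2.14), at 536.7 against 1122 CPM. EGFR, the epidermal growth factor receptor (chromosome 7, 55019021 to 55211628), was 1.80-fold lower (1.71 to 1.89), at 143.6 against 258.5 CPM. WNT5A, a non-canonical Wnt ligand, was 2.06-fold lower (1.54 to 2.79), the sialidase NEU3 2.07-fold lower (1.49 to 2.88) and the hyaluronan-binding CEMIP 1.85-fold lower (1.60 to 2.14). TIGIT, a lymphocyte receptor, had 215.24 estimated counts in the vector library and 0 in the PKP2 library, at least 70.9-fold lower against the floor of 3 counts, with 57.15 as the lower end of the counting interval, but its count was fractional and is uncertain. LINC03105 at 2.35-fold, TVP23C-CDRT4 at 2.03-fold, RGP1 at 1.85-fold and FMN1 at 1.80-fold lower were fractional too.

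The difference between the libraries followed transcript length and GC content over the whole transcriptome. Among 10797 genes with a mean of 5 CPM or more, the shortest of 5 equal groups by longest transcript had a median difference of 0.13 and the longest one -0.16. From the lowest to the highest GC group the median went from -0.12 to 0.09. Spearman's rho across genes, which are not independent replicates, was -0.52 with length and 0.41 with GC content. An additive trend on both accounted for 30.2% of the variance of the differences. Long genes named as lower lie on the side the length trend favours, among them MUC5AC (17448 nucleotides), MUC5B (17911), EGFR, CEMIP and the integrins. So do short genes named as higher, such as CXCL1 and the ribosomal protein genes. With the length and GC trend removed, MUC5AC stayed at -1.68, MUC5B at -0.81, CEACAM6 at -1.08, EGFR at -0.69 and CFB at 1.06 on the log2 scale.

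**Figure D2:**
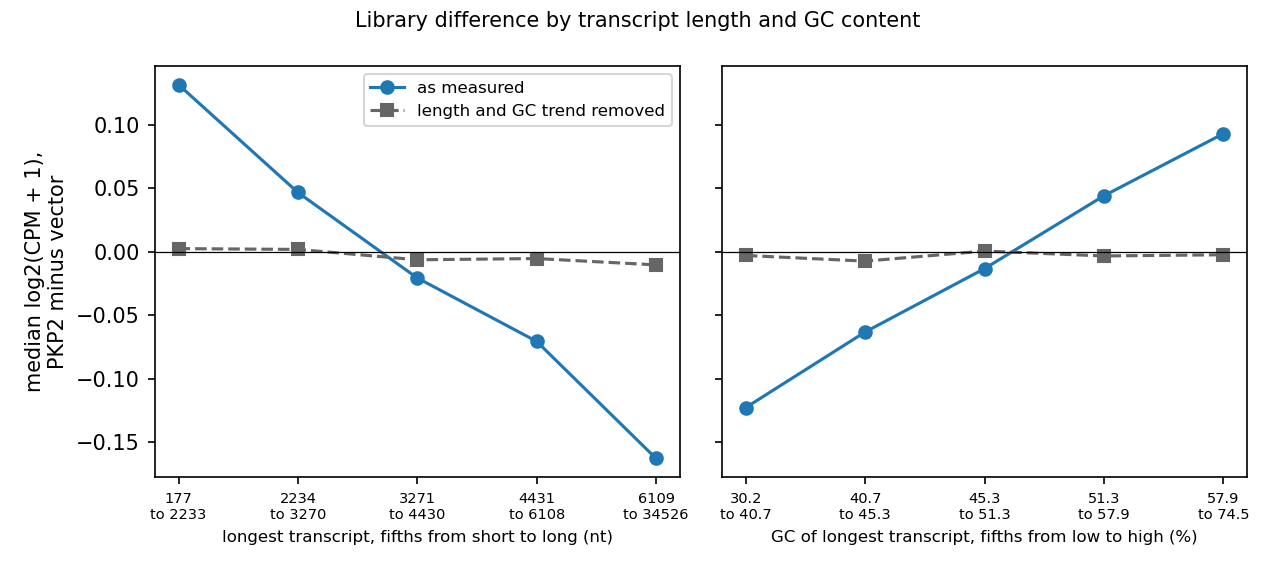
Median difference in log2(CPM + 1), PKP2 minus vector, in 5 equal groups of genes by length of the longest transcript (left, in nucleotides) and by its GC content (right, in percent). Blue circles are values as measured, from 0.13 in the shortest to -0.16 in the longest genes, and grey squares are values with the trend removed, which lie near 0.

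NF-kappaB target and cytokine genes stood highest of the fixed lists. Of 21 expressed members, 18 were higher in the PKP2 library, 16 with a counting interval above 1, and 6 were at least 1.5-fold higher. The neutrophil-attracting chemokines CXCL1, CXCL3 and CXCL8 were 1.57-fold (1.497 to 1.65), 1.54-fold (1.39 to 1.71) and 1.40-fold (1.33 to 1.47) higher. The adhesion molecule ICAM1 was 1.84-fold higher (1.39 to 2.44). BIRC3 had a ratio of 0.905 (0.842 to 0.973), the 1 member with an interval below 1, and was picked after its value was seen. Its difference was 0.01 instead of -0.14 with the length and GC trend removed. The list median was 0.37, with a 95% counting interval of 0.32 to 0.44, above all 10000 random lists (percentile 100), and 0.35 with the length and GC trend removed. Ribosomal protein genes, a list on RNA quality, were higher too in 32 of 32 cases (percentile 100). Fibroblast markers had a median of 0.27 at percentile 99.0, with a counting interval of -0.04 to 0.40. Interferon-stimulated genes had a median of 0.13 at percentile 95.4, inside the range of most random lists. IRF9, part of the interferon-activated transcription factor, was 1.26-fold higher (1.01 to 1.57) and USP18, an interferon-induced protease, had an interval of 0.947 to 1.33 around a ratio of 1.12. With the trend removed the interferon list reached 0.16 at percentile 99.6, with IRF9 at 0.17 instead of 0.30 and USP18 at 0.08 instead of 0.16. Over the 8 members with a mean of 5 CPM or more the list median was 0.07 at percentile 81.6.

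**Figure D3:**
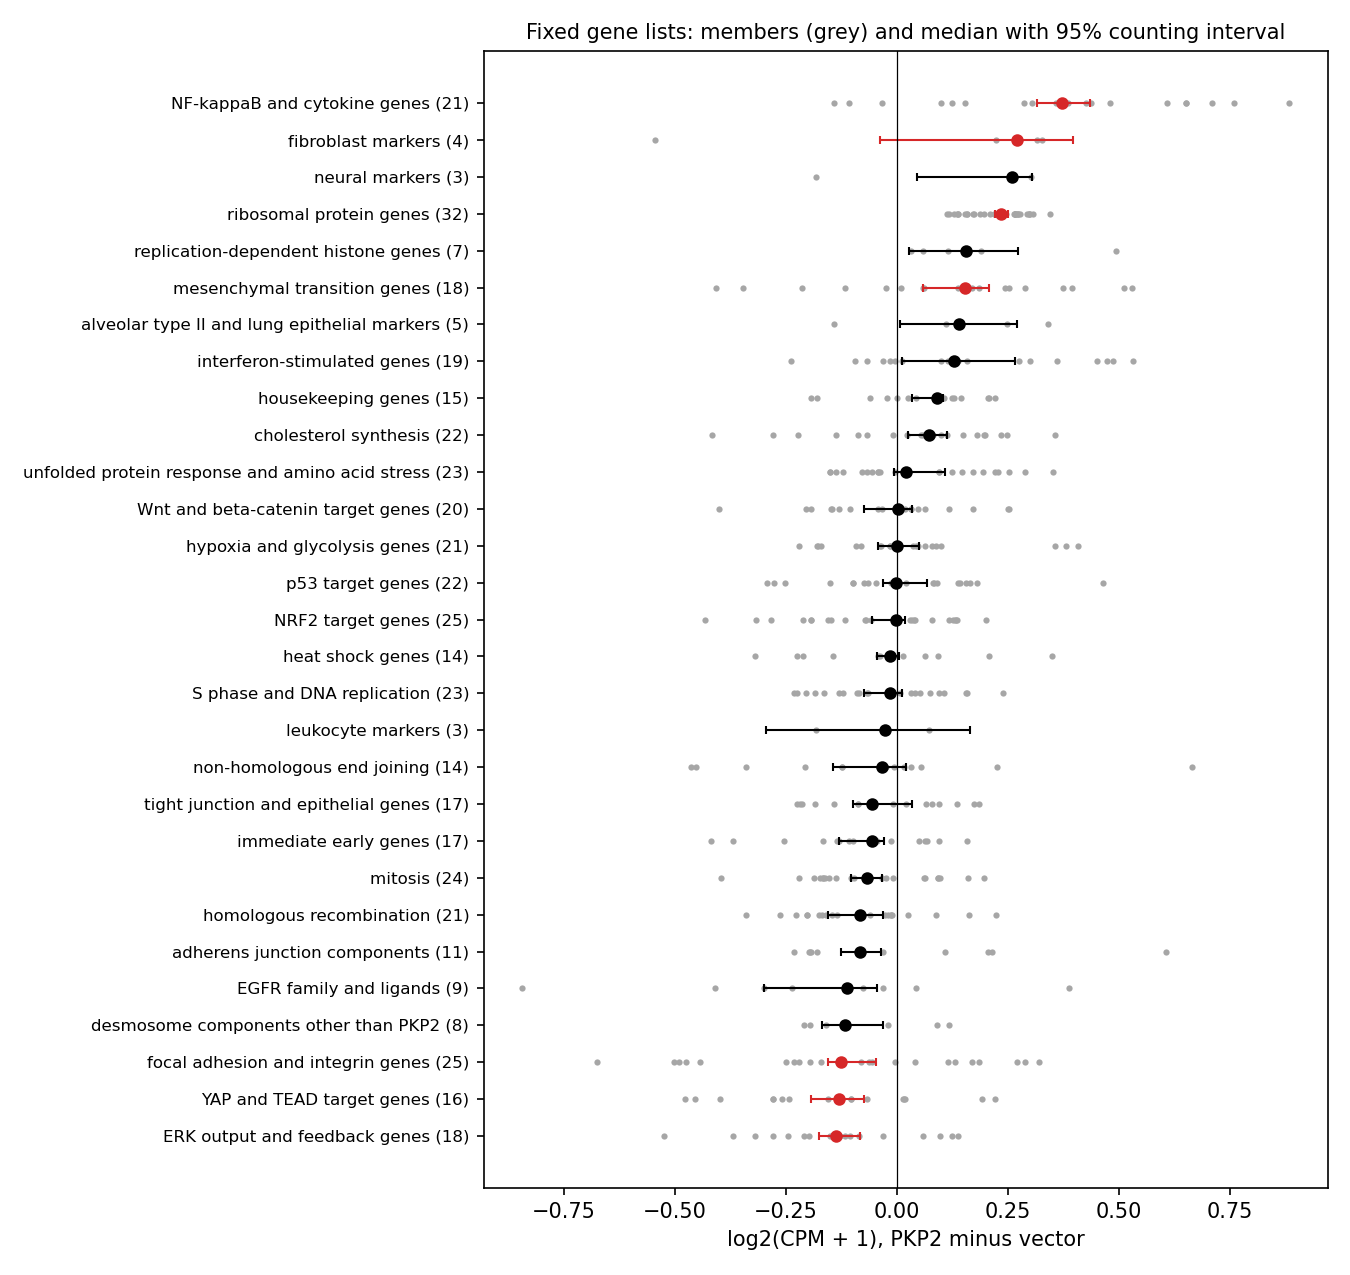
Difference in log2(CPM + 1), PKP2 minus vector, of the expressed members of 29 fixed lists (grey points, with their number after the list name) and each list's median with its 95% counting interval. Red medians lie outside the central 95% of the random lists, with NF-kappaB and cytokine genes at 0.37 and ERK output and feedback genes at -0.14 at the ends.

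Published work on PKP2 in lung cancer concerns beta-catenin and the DNA ligase gene LIG4, so these were looked up whatever their values. LIG4, the ligase of non-homologous end joining (chromosome 13, 108207439 to 108218368), was 1.63-fold higher in the PKP2 library (1.38 to 1.93), at 21.8 against 13.4 CPM, from 366 and 227 counts. Of the 14 end-joining genes it was the 1 at least 1.5-fold higher. The catalytic kinase subunit PRKDC was 1.38-fold lower (1.34 to 1.42), RIF1 1.37-fold lower (1.27 to 1.49) and XRCC4, the binding partner of LIG4, 1.29-fold lower (1.06 to 1.57). With the length and GC trend removed PRKDC lay at -0.27 instead of -0.46 and RIF1 at -0.20 instead of -0.45. The list median was -0.03 at percentile 25.8. Homologous recombination genes had a median of -0.08 at percentile 6.93, and 17 of 21 were lower, among them BRCA1 by 1.20-fold (1.12 to 1.29) and XRCC2 by 1.28-fold (1.12 to 1.46). With the trend removed this median was 0.02, and BRCA1 lay at -0.10 instead of -0.26.

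Wnt target genes were centred on 0. Their median was 0.00 at percentile 54.2, with 10 of 20 members higher and 10 lower. CTNNB1, which encodes beta-catenin, was 1.02-fold lower with an interval of 0.979 to 1.07. The feedback target AXIN2 was 1.11-fold lower (0.962 to 1.29), so neither differed detectably at this depth. With the trend removed CTNNB1 lay at 0.06 instead of -0.03. MYC was 1.14-fold lower (1.10 to 1.20) and CCND1 1.08-fold lower (1.05 to 1.11). EPHB2 was 1.19-fold higher (1.13 to 1.26), and TNFRSF19 1.37-fold (1.06 to 1.79) and RNF43 1.16-fold (1.05 to 1.27) lower. Removing the trend enlarged the difference of MYC, to -0.28 from -0.19, and of EPHB2, to 0.37 from 0.25. It reduced that of CCND1, to -0.08 from -0.11, of TNFRSF19, to -0.33 from -0.40, and of RNF43, to -0.14 from -0.20.

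The EGFR family list did not stand apart, whereas genes read as ERK output did, on the lower side. EREG was 1.33-fold lower (1.27 to 1.39) and AREG 1.24-fold lower (1.13 to 1.35), whereas HBEGF was 1.36-fold higher (1.04 to 1.79). The EGFR family list had a median of -0.11 at percentile 7.91, at percentile 8.62 with the trend removed and at 11.7 when matched on length. At a mean of 5 CPM or more its 7 members had a median of -0.24 at percentile 0.42. ERK output and feedback genes had a median of -0.14 at percentile 0.88, with 14 of 18 members lower, 9 with an interval below 1 and 1 above. EMP1 was 1.46-fold lower (1.29 to 1.65), and the ERK phosphatase DUSP5 1.22-fold lower (1.13 to 1.32). IER3, the member above 1, had a ratio of 1.10 (1.05 to 1.15), but a difference of -0.04 instead of 0.14 with the trend removed. The ERK phosphatase DUSP6 had a ratio of 1.09 (0.978 to 1.22), and both were picked after their values were seen. Immediate early genes had a median of -0.06 at percentile 14.9, and EGR1 was 1.34-fold lower (1.28 to 1.40). With the length and GC trend removed their median was -0.13 at percentile 0.17, and over the 15 members with a mean of 5 CPM or more it was -0.10 at percentile 5.54.

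Integrins and YAP targets were lower as lists. Of 25 focal adhesion and integrin genes, 17 were lower and 12 had a counting interval below 1. The laminin receptor subunit ITGA6 was 1.60-fold lower (1.52 to 1.69), the collagen receptor subunit ITGA2 1.42-fold lower (1.34 to 1.51), ITGAV 1.41-fold lower (1.34 to 1.48) and the laminin chain LAMA3 1.40-fold lower (1.25 to 1.58). The list median was -0.13 at percentile 0.29. These genes have long transcripts, with a median of 5479 nucleotides, and with the trend removed the list lay at -0.06 and percentile 3.68, no longer apart, with ITGA2 at -0.32 instead of -0.50 and ITGAV at -0.31 instead of -0.49. YAP and TEAD targets had a median of -0.13 at percentile 1.59, with ANKRD1 1.44-fold (1.16 to 1.78) and PTPN14 1.38-fold (1.26 to 1.51) lower. Of the 16 members, 9 had an interval below 1 and 2 above, FJX1 with a ratio of 1.15 (1.02 to 1.29) and GADD45A with 1.17 (1.03 to 1.33). CCN1 at 1.01 (0.964 to 1.07) and CCN2 at 1.01 (0.954 to 1.07) did not differ detectably, and these 4 genes were picked after their values were seen. Over the 15 members with a mean of 5 CPM or more the list was at percentile 5.74, no longer apart. With the trend removed the YAP list lay at -0.11 and percentile 0.49, still apart, and it was at percentile 1.23 when matched on length. ANKRD1 then lay at -0.51 instead of -0.48, PTPN14 at -0.26 instead of -0.45, FJX1 at 0.07 instead of 0.19 and GADD45A at 0.10 instead of 0.22.

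Junction genes outside the desmosome did not stand apart, while mesenchymal genes did. Adherens junction components had a median of -0.08 at percentile 10.8, and of -0.13 at percentile 3.16 over the 10 members with a mean of 5 CPM or more. CDH2, which encodes N-cadherin, was 1.16-fold higher (1.07 to 1.27), NECTIN3 was 1.18-fold lower (1.11 to 1.25) and VCL 1.15-fold lower (1.11 to 1.19). Tight junction and epithelial genes had a median of -0.06 at percentile 13.0, and of -0.01 without the expression filter, with CLDN12 1.17-fold lower (1.04 to 1.32). Mesenchymal transition genes had a median of 0.15 at percentile 99.3, and 13 of 18 were higher. Fibroblast markers, at 0.27 and percentile 99.0, and ribosomal protein genes, with 32 of 32 higher, lay on the same side. The members with the largest differences went both ways. TAGLN (fractional count) was 1.45-fold (1.26 to 1.67) and TWIST1 1.38-fold (1.02 to 1.89) higher, and ZEB1 was 1.34-fold (1.19 to 1.51) and fibronectin gene FN1 1.27-fold (1.24 to 1.31) lower. With the trend removed the mesenchymal list lay at 0.15 and percentile 99.87, and it was at percentile 99.55 when matched on length. The differences of single members were then smaller for TWIST1 (0.25 against 0.39), ZEB1 (-0.24 against -0.41) and FN1 (-0.16 against -0.35). VCL then lay at -0.04 instead of -0.20 and CLDN12 at -0.15 instead of -0.23, and the adherens junction median was -0.04.

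Proliferation, stress and metabolism lists lay inside the range of most random lists. S phase genes had a median of -0.02 at percentile 41.8, with GINS2 1.18-fold higher (1.08 to 1.30) and RRM2 1.15-fold lower (1.11 to 1.20). Mitosis genes had a median of -0.07 at percentile 9.89, with MKI67 1.32-fold lower (1.28 to 1.36), and lay at percentile 0.47 when random lists were matched on length too. With the length and GC trend removed, however, their median was -0.03 at percentile 29.2 and MKI67 lay at -0.22 instead of -0.40. The p53 targets had a median of 0.00 at percentile 55.1, and BBC3, a pro-apoptotic target, was 1.41-fold higher (1.18 to 1.69). NRF2 targets, which are constitutively active in this KEAP1-mutant line, had a median of 0.00 at percentile 39.7, and the cystine transporter gene SLC7A11 was 1.35-fold lower (1.29 to 1.41). With the trend removed the NRF2 list lay at -0.09 and percentile 0.13, though SLC7A11 moved from -0.43 to -0.20. The unfolded protein response list had a median of 0.02 at percentile 67.1, with the transcription factor CEBPB 1.28-fold higher (1.19 to 1.38). Heat shock genes had -0.02 at percentile 37.2, with the small chaperone HSPB1 1.28-fold higher (1.22 to 1.33) and HSPA8 1.17-fold lower (1.15 to 1.19). Hypoxia and glycolysis genes had a median of 0.00 at percentile 48.0, with ANGPTL4 1.31-fold higher (1.05 to 1.64) and the glycolytic regulator PFKFB3 1.17-fold lower (1.13 to 1.20). Cholesterol synthesis genes had a median of 0.07 at percentile 97.0, with INSIG1 1.19-fold higher (1.09 to 1.30), and at percentile 99.6 with the trend removed. Among the genes named as higher here, the trend-free differences were 0.27 for BBC3, 0.19 for CEBPB, 0.16 for HSPB1 and 0.20 for ANGPTL4, against 0.47, 0.35, 0.35 and 0.36 with it.

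Few markers of lung epithelium and of other cell types were expressed. Of the lung epithelial, fibroblast, leukocyte and neural markers, 4, 3, 1 and 2 had a mean of 5 CPM or more. Lung epithelial markers had a median of 0.14 at percentile 92.1 over 5 genes, 4 higher and 1 lower. LPCAT1 was 1.19-fold higher (1.12 to 1.26) and ABCA3 1.10-fold lower (1.03 to 1.19). Leukocyte markers had a median of -0.03 at percentile 42.0 over 3 genes, none with an interval that excludes 1, and of -0.16 with the length and GC trend removed. Neural markers had a median of 0.26 at percentile 96.3 over 3 genes, with NEFL 1.26-fold higher (1.03 to 1.54), and of 0.12 at percentile 83.4 with the trend removed. Fibroblast markers had a median of 0.27 at percentile 99.0 over 4 genes, where COL5A1 was 1.26-fold (1.19 to 1.33) and COL1A1 1.28-fold (1.01 to 1.61) higher and FBN1 1.49-fold lower (1.28 to 1.73). The counting interval of the fibroblast median was -0.04 to 0.40, which includes 0. Without the expression filter the fibroblast percentile was 46.3, and the medians of the lung epithelial and neural markers were 0.08 and 0.15.

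Among the lists on RNA quality, all 32 ribosomal protein genes were higher in the PKP2 library, each with a counting interval above 1. RPL32 was 1.27-fold higher (1.24 to 1.30) and RPLP2 1.24-fold higher (1.20 to 1.27). The median was 0.24 at percentile 100, and 0.14 with the length and GC trend removed, when RPLP2 lay at 0.06 instead of 0.31. Replication-dependent histone genes had a median of 0.15 at percentile 90.7, 0.09 without the expression filter and -0.06 with the trend removed. Housekeeping genes had a median of 0.09 at percentile 96.6, and of 0.05 with the trend removed, with HPRT1 1.17-fold higher (1.09 to 1.26) and POLR2A 1.14-fold lower (1.09 to 1.20). In all, 7 of 29 lists stood apart, 4 higher, among them fibroblast markers with a counting interval that includes 0, and 3 lower. By chance 1.45 would if the genes within a list varied as independently as those of a random list. That was not tested, so 7 against 1.45 does not measure an excess. No list member reached the 2-fold rule.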

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

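No result met the fixed rules for a closer look, which need more samples per group or data outside the main measurement. The patterns weighed here were chosen after the values were seen. The length and GC tests and the test of low members were written before their results, and those of other cell types, counting error, the neighbouring gene and PKP2 overexpression after.

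NF-kappaB and cytokine genes were higher in the PKP2 library, as were ribosomal protein genes (32 of 32, percentile 100). Fibroblast markers had a median of 0.27 at percentile 99.0, with a counting interval of -0.04 to 0.40. With the length and GC trend removed the NF-kappaB median was 0.3461, against 0.37 without. It was at percentile 100 when matched on level and length, so that trend is not the whole cause. Members with a mean of 5 CPM or more gave 0.3308, with a lower interval end of 0.2694, which argues against few counts. COL5A1 was at 179.4 CPM in the PKP2 library and at 142.8 CPM in the vector library. COL3A1, LYZ, LAPTM5 and LCP1 together held 1.258 CPM in the PKP2 library, against a summed gain of 657.3 CPM in the NF-kappaB list. These low genes were picked from the fibroblast and leukocyte lists after their values were seen, so their sum cannot decide on cells of another type. Among the expressed fibroblast markers 3 were higher and 1 lower, and among the leukocyte markers 1 was higher and 2 lower. Cells of another type were therefore not excluded. A response to PKP2 overexpression stays open. That 0 other lists had a median as high was fixed in advance, since the NF-kappaB list was weighed because it stood highest. With 1 library per group a response to PKP2 cannot be told apart from a difference between any pair of cultures.

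LIG4 was higher in the PKP2 library. Its difference was 0.7729 with the length and GC trend removed, larger than the 0.67 without, so that trend works against it. The lower end of its counting interval was 1.378, beyond counting error. Reads spilling over from its neighbour ABHD13 are argued against by that gene's ratio of 0.8321, with an upper end of 0.9753. Of the 500 whole-count genes nearest in level 0 had as large a positive difference. Whole-count genes a little further in level did, such as CFB at 1.11 (20.1 against 8.77 CPM) and COXFA4L3 at 0.84 (26.4 against 14.3 CPM). The count of 0 therefore depends on how many neighbours are taken. PKP2 overexpression cannot be told apart from a difference between cultures without replicates.

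EGFR and the integrin genes were lower in the PKP2 library. EGFR lay at -0.6858 with the trend removed, against -0.84, so length and GC are not the whole cause for this gene. For the integrin list the trend may account for much of the pattern: its median went from -0.13 to -0.06, just under 50% of its size, the bound set beforehand, and its percentile matched on level and length was 12.26. For EGFR, 0 of the 500 whole-count genes nearest in level had as large a negative difference. EGFR was already among the 12 genes with the largest negative differences, so this count was largely fixed in advance. PKP2 overexpression stays open because a difference between cultures cannot be told apart from it.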

How the results depend on the processing

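The choices about fractional counts, the length and GC trend and length-matched lists were made after seeing the data. PKP2 kept its direction, from 3.25 to 3.29. Against 11 genes at least 2-fold higher and 13 lower, the counts were 58 and 52 with a pseudocount of 0.1, 4 and 4 with 5, 6 and 5 at a mean of 5 CPM or more, 94 and 101 at 1.5-fold, and 4 and 1 at 4-fold. Leaving out fractional counts, so that fewer genes were counted, gave 3 and 4, and removing the trend gave 7 and 11, where 3 and 4 of the genes counted before had no length and GC record and dropped out for that reason. The median and the trimmed mean of the log ratios were -0.0015 and -0.00056, and setting either to 0 left 11 and 13. No filter gave 11 and 13 too, but this was fixed in advance. On the log2(CPM + 1) scale a gene under 1 CPM in both libraries cannot reach the 2-fold rule. For the pseudocounts and the trend the cause was not tested. The library correlation was 0.992 at a mean of 5 CPM or more, against 0.994. Between 6 and 10 lists stood apart over these settings, against 7. Removing the trend moved 7 of 29 list medians and 43 of 136 named genes beyond their counting intervals. Rescaling to 1000000 gave no value, since CPM already sums to that. No paired analysis was possible because each group has 1 library, and no library could be left out. Depth limits genes near 1 CPM: IL1A, picked after its value was seen, with 22 and 33 counts, had a ratio of 1.52 with an interval of 0.858 to 2.73.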

Other observations

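Families grouped by gene name were described after their values were seen. Of the 4 expressed CEACAM genes, CEACAM5, CEACAM6 and CEACAM1 had counting intervals below 1. CEACAM5, the classical carcinoembryonic antigen, was 2.23-fold lower in the PKP2 library (1.48 to 3.43) from 79 and 35 counts, and CEACAM1 was 1.48-fold lower (1.18 to 1.86). CEACAM19 had a ratio of 1.14 (0.980 to 1.33). Of 7 expressed mucins, MUC5AC, MUC5B and MUC13 had intervals below 1 and 0 had one above. MUC13, a membrane mucin, was 1.20-fold lower (1.12 to 1.29), and MUC1 had a ratio of 1.16 (0.826 to 1.65). FCGBP, a mucus protein that binds mucins, had a ratio of 0.565 (0.492 to 0.649) and was picked after its value was seen.

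The following genes were also picked after their values were seen, and no group of them was tested. C3 had a ratio of 1.37 (1.31 to 1.45), C1R of 1.46 (1.29 to 1.66) and C1S of 1.26 (1.13 to 1.40). LCN2 was at 1.47 (1.31 to 1.65), with a difference of 0.32 instead of 0.54 once the length and GC trend was removed, and IL32 at 1.68 (1.54 to 1.83). IL6, already counted as a member of the NF-kappaB and cytokine list, rested on 24 and 58 counts, with a ratio of 2.44 (1.49 to 4.11). Among genes of antigen presentation, HLA-E was at 1.17 (1.08 to 1.27) and HLA-F at 1.62 (1.04 to 2.54), with differences of 0.15 and 0.35 once the length and GC trend was removed, against 0.23 and 0.50. Among the 4 expressed metallothioneins, MT2A was at 1.61 (1.56 to 1.66) with a difference of 0.48 once that trend was removed, against 0.68. MT1X was at 1.16 (1.09 to 1.24), with a difference of 0.09 once the trend was removed, against 0.22. MT1F was at 1.27 (0.865 to 1.89) and MT1A at 1.45 (0.694 to 3.09), with intervals that include 1.

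Genes with a mean of 5 CPM or more and whole counts gave 21 at least 1.5-fold higher and 37 lower. With the length and GC trend removed as well, 13 and 12 stayed past that size, and 1 of the 37 had no length and GC record. These values were computed after the trend was seen.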
